A study of Caenorhabditis elegans with 6 samples.

How the data were processed

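Each table holds read counts per annotated transcript as deposited by the authors, 1 table per library, with a sense and an antisense column in 5 libraries and a single column in the first untreated library. That column was read as the sum of both strands, because it holds reads of microRNA and ribosomal RNA genes, which are sense in the other libraries, and of genes such as chk-2, which are antisense there. The labels do not state this, and the comparisons with that library rest on it. The reads had been aligned with Bowtie2 per the submitters' processing notes; its version, the genome build, the annotation release and the counting tool are not given in the sources used here. The values are whole numbers and were used without further filtering. The columns carry no names. The strand was judged from microRNAs, whose antisense share was 0.335% (Wilson interval 0.284 to 0.395) after lin-15b RNAi, 0.417% (0.364 to 0.478) on HT115, 0.356% (0.304 to 0.416) in P0, 0.207% (0.171 to 0.251) in F1 and 0.202% (0.171 to 0.238) in F3.

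Counts were summed over the transcripts of a gene. In P0, 506 genes had 2 numbered transcripts and at least 200 antisense reads; in 6 of them the 2 counts were equal, and in 500 they differed by at most 0.25 of their sum, which is how reads divided at random over shared sequence would look. The tables of the first 2 libraries have 56029 lines and 45162 genes, those of the other 4 have 56377 lines and 45510 genes. Per library 3 lines carry no gene. They hold 0.000106% to 0.000296% of the reads and were left out. Of the 45510 genes, 44852 were found in the Ensembl release 115 annotation of WBcel235 and 658 were not; 44187 took their symbol from the RefSeq gene table.

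For the oma-1 libraries, antisense counts were divided by the antisense total of the library and compared with HT115. The comparison of lin-15b RNAi with the first untreated library, and that of the 2 libraries without RNAi, used the sum of both strands over the genes found in both tables. Log2 ratios had 0.5 added to each count. A gene was measured when it reached 25 CPM (counts per 1000000 reads) in the higher library of the comparison, and was listed when it differed at least 4-fold. Intervals of levels are exact Poisson intervals, those of folds are exact conditional binomial intervals, and those of shares are Wilson intervals, all at 95%. A fold against 0 reads is given as a bound, with 3 counts in place of 0. The place of a gene is its percentile among the 500 measured genes closest in abundance.

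The 21 gene lists were written from general knowledge, by gene name or by name prefix, before the data were examined: oocyte and early embryo regulators, P granule components, small RNA pathway genes, meiosis and synapsis, kinetochore, centrosome and mitosis, sperm, muscle, intestine, cuticle, neurons, ERGO-1 targets, mutator targets, synMuv genes, stress response, histones, ribosomal proteins, microRNAs, piRNAs, F-box and BATH genes, chemoreceptors and X-linked genes. Entries without a matching gene were drh-2, mfp-2, fatp-4, daf-21 and 5 of the 14 ERGO-1 entries. The median log2 ratio of the measured members was placed among 10000 random lists of the same size drawn from 20 abundance bins, and a list was called outside below percentile 2.5 or above percentile 97.5. Lists with fewer than 5 measured members were not placed. With 21 lists and 5 comparisons some fall outside by chance.

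The genes named in the report follow a rule. It takes 12 genes chosen in advance (oma-1, oma-2, lin-15B, lin-15A, wago-4, pos-1, mex-5, gld-1, pgl-1, csr-1, ego-1 and hrde-1), the 10 most abundant genes of the libraries without RNAi, and the 10 highest and 10 lowest log2 ratios of each comparison. It adds up to 4 members of each list outside the random range, the 2 most abundant and the 2 with the largest ratio, and up to 10 genes that differ 4-fold the same way in all 3 generations. The 3 genes on each side of oma-1 were added as neighbours.

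The 4-fold rule, the intervals and the list percentile were tried on simulated counts. These counts hold counting error alone and no variation between libraries. Counts were drawn from the depth and abundance of each pair of libraries, with 200 genes given a known difference. Of the genes set 8-fold or 16-fold apart 100% were listed, of those set 2-fold apart 0%, and 0 unchanged genes were listed in any comparison. No fold closer to 4 was set, so counting error alone at this depth could hardly have given other shares. The 95% intervals held the true fold for 93.9% to 95.4% of genes, and a list of 35 genes moved by 0.3 came out at percentile 100. The number of genes expected to differ the same way in all 3 generations was taken from 20 simulated sets of libraries that share a control and differ by counting error alone.

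Alternatives chosen in advance were median-of-ratios scaling, TMM scaling, totals without the 20 most abundant genes and the target, a pseudocount of 5, the other library without RNAi as reference over both strands, thinning to the smallest library, both strands in place of antisense, no minimum level, a minimum of 100 CPM, a 2-fold threshold, the list mean, lists without their prefix families and shares without the 20 most abundant genes. Chosen after seeing the data were antisense counts over the total of both strands, protein-coding genes only, lin-15B antisense counts against HT115, and genes with at least 90% antisense reads after lin-15b RNAi. The programs were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors.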

Results

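Small RNAs bound to WAGO-4, an Argonaute protein of the Caenorhabditis elegans germline, were sequenced after immunoprecipitation with an anti-FLAG antibody. The animals carried WAGO-4 tagged with FLAG and GFP and were collected as young adults at 20 °C, according to the labels. There were 6 libraries, 1 per group, all from precipitates. None is an input or untagged control, so levels describe the precipitate and not enrichment over other small RNAs. A first untreated library was paired with a library from animals given RNAi against lin-15b. A library from animals on HT115, the bacterial strain that delivers double-stranded RNA (dsRNA) by feeding, served as the reference without RNAi for animals exposed to oma-1 dsRNA (P0) and for their F1 and F3 descendants. The gene-assigned reads numbered 11309227 in the first untreated library, 9439667 after lin-15b RNAi, 9500363 on HT115, 8667735 in P0, 9793525 in F1 and 10074688 in F3. With 1 library per group no difference has a replicate check and no p-value is given. Intervals are 95% intervals that cover counting error only and leave out variation between libraries. They may be too narrow even for counting error, because PCR reads without molecular identifiers are not independent molecules.

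The 5 libraries with strands kept apart were mostly antisense to annotated genes, the orientation of secondary small interfering RNAs that RNA-dependent RNA polymerases copy from target transcripts. The antisense share was 77.8% (Wilson interval 77.8 to 77.8) on HT115, 69.6% (69.6 to 69.6) in P0, 55.6% (55.6 to 55.7) in F1, 72.5% (72.5 to 72.6) in F3 and 69.98% (69.95 to 70.005) after lin-15b RNAi. Levels below are counts per 1000000 gene-assigned antisense reads (CPM) for the oma-1 libraries and HT115. Comparisons with the first untreated library, whose single count column was read as the sum of both strands, use both strands. The labels also carry growth notes that differ between these libraries (embryos held at several temperatures, larvae without food, embryos after ultraviolet light), and these notes could not be reconciled with the young adult stage.

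Most listed genes of the germline and the early embryo reached 25 antisense CPM in the HT115 precipitate, whereas few somatic markers and sperm genes did. Each of the lists of germline and embryo genes held a small share of all antisense reads. Apart from sperm genes (0.0965%), shares ran from 0.787% (Wilson interval 0.780 to 0.793) for oocyte and embryo regulators to 2.69% (2.68 to 2.71) for kinetochore, centrosome and mitosis genes. All 35 oocyte and early embryo regulators and all 37 meiosis and synapsis genes reached 25 antisense CPM, as did 62 of 65 kinetochore, centrosome and mitosis genes. So did 24 of 28 P granule components, 55 of 67 small RNA pathway genes, 26 of 29 synthetic multivulva (synMuv) genes and 70 of 79 ribosomal protein genes. Of somatic markers, 0 of 37 intestine genes, 5 of 37 muscle genes, 6 of 181 cuticle genes, 9 of 157 neuron genes and 1 of 1299 chemoreceptor genes did so. Among the germline lists the sperm genes were the exception, with 7 of 78. On chromosome X, 124 of 2755 protein-coding genes reached 25 antisense CPM. For scale, 5866 of 45510 genes of all kinds reached that level on HT115 or in P0, and 5633 of these were protein-coding. The share for autosomal genes is not given here, so the X-linked count shows neither depletion nor enrichment. Protein-coding genes took 95.9% (Wilson interval 95.8 to 95.9) of antisense reads on HT115 and transposons 1.55% (1.54 to 1.56). After F31C3.14, a gene that lies opposite the ribosomal RNA gene rrn-3.1 and had 4231 CPM, the highest antisense levels were those of the microtubule regulators cls-2 (2755 CPM), klp-18 (2729.9) and klp-7 (2473), followed by wago-4 itself at 2400.5 CPM. F-box and BATH genes (71 of 434) and histones (22 of 81) include near-identical copies whose reads could be split between members.

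Over both strands the 10 most abundant genes on average across the 2 libraries without RNAi were rrn-3.1, rrn-1.2, rrn-1.1, the yolk gene vit-6, snrp-200, the meiotic kinase gene chk-2, F31C3.14, Y54G2A.19, figl-1 and wago-4. Several of these differed widely between the first untreated library and HT115: chk-2 stood at 6069.9 against 646 CPM, Y54G2A.19 at 5166 against 226, and figl-1 at 4760.3 against 382. Reads of vit-6 were almost all sense, with 0.0338% antisense on HT115. Protein-coding genes held 94.6% of both-strand reads (94.6 to 94.6) in the first untreated library and 89.6% (89.6 to 89.6) on HT115, ribosomal RNA genes 2.87% (2.86 to 2.87) and 5.83% (5.82 to 5.85), and microRNA genes 0.279% (0.276 to 0.282) and 0.522% (0.518 to 0.527).

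Antisense small RNAs against oma-1 were highest in the generation exposed to oma-1 dsRNA and were still above the reference in F1 and F3, the question this part of the design addresses. The gene oma-1 (WBGene00003864, WBcel235 chromosome IV, 8888976 to 8890999, plus strand) encodes a zinc-finger protein needed for oocyte maturation. It had 713 antisense reads on HT115 (96.5 CPM, exact Poisson interval 89.5 to 103.8), 8684 in P0 (1439.9 CPM, 1409.8 to 1470.5), 1725 in F1 (317 CPM, 302 to 332) and 1443 in F3 (197 CPM, 187 to 208). Relative to HT115 the level was 14.9-fold higher in P0 (13.8 to 16.14), 3.28-fold higher in F1 (3.01 to 3.59) and 2.05-fold higher in F3 (1.87 to 2.24), and in each generation 0 of the 500 genes of similar abundance had a ratio as high. The F1 level was 0.220 times that of P0 (0.209 to 0.232), and the F3 level was 0.624 times that of F1 (0.581 to 0.669). Antisense reads made up 55.6% of the F1 library against 72.5% in F3, so division by the antisense total raises F1 relative to F3. Over both strands oma-1 had 252 CPM in F1 (242 to 262) and 190 in F3 (181 to 199), a smaller fall. The remaining libraries held 105 antisense CPM (97.4 to 113, lin-15b RNAi) and, over both strands, 107 CPM (101 to 113, first untreated library). With both strands counted the log2 ratios to HT115 were 3.26 in P0, 1.16 in F1 and 0.75 in F3, against 3.90, 1.71 and 1.03 for antisense reads alone, so that in F3 the level was then under 2-fold.

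**Figure D1:**
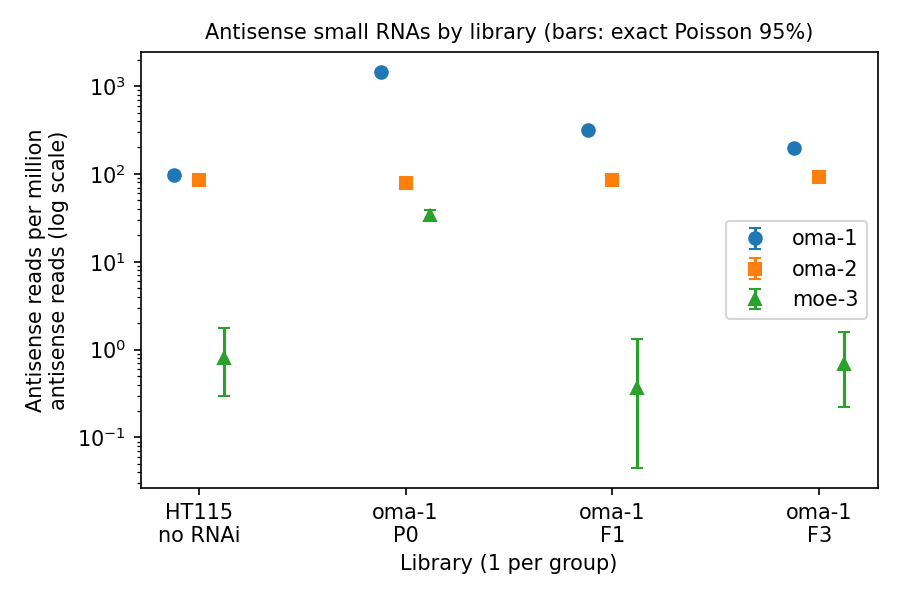
Antisense CPM (vertical log axis) of oma-1, oma-2 and moe-3 in the HT115, P0, F1 and F3 libraries, with exact Poisson 95% intervals as bars. Levels of oma-1 go from 1439.9 in P0 to 197 in F3 against 96.5 on HT115, those of oma-2 lie between 79.4 and 92.2 in all 4 libraries, and moe-3 is above 1 CPM in P0 alone.

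The paralog and the neighbours of oma-1 stayed near the HT115 reference. The level of oma-2 (WBGene00003865, chromosome V, 8029439 to 8031214, plus strand), the paralog that acts with oma-1 in oocytes, was 84.8 CPM on HT115, 79.4 in P0, 86.1 in F1 and 92.2 in F3, and its folds of 0.936 (0.830 to 1.06), 1.01 (0.898 to 1.14) and 1.09 (0.974 to 1.21) did not differ from 1 at this depth. Downstream of oma-1, spr-2 stood at 0.787 times the reference in P0 (0.706 to 0.876), 0.987 in F1 and 0.985 in F3, C27B7.2 at 0.838 (0.725 to 0.966), 0.893 and 0.891, and rad-54.L2 at 1.05, 1.04 and 1.09. Upstream, npax-4 had 0 antisense reads in these 4 libraries and C09G9.8 and C09G9.5 had at most 3, too few for a ratio. Against the first untreated library, over both strands, both spr-2 (log2 1.18, 1.47 and 1.55) and rad-54.L2 (-0.34, -0.54 and -0.25) turned to the other side of 0 in all 3 generations. In that setting spr-2 exceeded oma-1 in F1 and F3 (1.25 and 0.84), and oma-2 lay below the reference, at log2 -0.62, -0.39 and -0.67 in P0, F1 and F3.

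In P0, besides oma-1, only moe-3 was at least 4-fold higher than on HT115 among 5866 genes, and only vang-1 was at least 4-fold lower. The gene moe-3 (WBGene00003388, chromosome II, 13160415 to 13165733, minus strand) encodes a zinc-finger protein of the same family as oma-1. It had 207 antisense reads in P0 against 6 on HT115, a fold of 42.3 (19.1 to 117), 2 in F1 and 5 in F3. Its end overlaps F32A11.1 on the other strand (13157329 to 13160462), a gene outside the naming rule, chosen for this overlap once the moe-3 level was seen, whose antisense level was 99.0 CPM in P0 and 98.8 on HT115. Reads antisense to moe-3 in the overlap are sense to F32A11.1, so that antisense level does not bear on them. Sense reads of F32A11.1 numbered 219 in P0, where 186 were expected at HT115 levels. The planar polarity gene vang-1 was 4.45-fold lower in P0 (3.61 to 5.52), and the muscle gene unc-22 stood at 0.369 times the reference (0.278 to 0.485). Next came rrn-4.3 (0.515), sma-1 (0.527), Y7A5A.6 (0.547), F49B2.3 (0.556), pyr-1 (0.610), npr-11 (0.630), din-1 (0.632) and W07E11.1 (0.637). On the higher side the small nucleolar RNA gene K07C10.2 (2.91-fold, 2.67 to 3.16) and the X-linked gene F39C12.1 (2.49-fold, 2.23 to 2.79) followed oma-1, together with F02D10.11 (3.097-fold), ZK622.6, F59C12.7, Y53C10A.16 and F10D2.15, which lie opposite transfer RNA (tRNA) or small nuclear RNA genes.

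Of the 21 gene lists, 7 lay outside the range of random lists in P0, all with small medians. P0, F1 and F3 share the HT115 library, so a trait of that library alone would move their lists alike. Against the first untreated library, HT115 itself lay the opposite way for ribosomal (percentile 100), kinetochore (98.3), F-box (1.7) and X-linked lists (0). Small RNA pathway genes lay the same way (98.8), and ERGO-1 targets (90.6) and oocyte regulators (85.0) lay within the range. Ribosomal protein genes were lower (median log2 ratio -0.20, 3 higher and 67 lower), among them rpl-4 at 0.721 and rps-8 at 0.727 times the reference, and rpl-34 (0.811) and rpl-13A (0.860). Targets of ERGO-1, the Argonaute of a primary small RNA class, were lower (-0.23, 1 higher and 7 lower), with E01G4.5 at 0.786, C36A4.11 at 0.790 and C44B11.6 at 0.835. Kinetochore, centrosome and mitosis genes (-0.06, 20 higher and 42 lower) included knl-2 at 0.822, par-1 at 0.832 and klp-7 at 0.850, and oocyte and embryo regulators (-0.06, 13 higher and 22 lower) included etr-1 at 0.817 and mex-3 at 0.864. F-box and BATH genes were higher (0.12, 64 higher and 12 lower; fbxa-11 1.503, fbxb-24 1.40), as were small RNA pathway genes (0.04, 36 higher and 19 lower; rrf-2 1.29, mut-15 1.17, prg-1 1.05) and X-linked genes (0.09, 91 higher and 53 lower). Germline regulators named in advance stood at 1.00 times the reference for wago-4, 0.980 for pos-1, 0.925 for mex-5, 1.08 for gld-1, 1.06 for pgl-1, 1.01 for csr-1, 1.11 for ego-1 and 0.964 for hrde-1. With totals without the 20 most abundant genes and the target, 2 genes were at least 4-fold lower in place of 1 and the X-linked list was within the random range (percentile 87.1), as was the small RNA pathway list by its mean (95.2). With no minimum the X-linked list lay on the other side (0). Against the first untreated library over both strands, 216 genes were higher and 183 lower. There the oocyte, kinetochore, ribosomal, F-box and X-linked lists lay on the other side of the random lists, and the ERGO-1 targets lay within them (percentile 38.3).

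**Figure D2:**
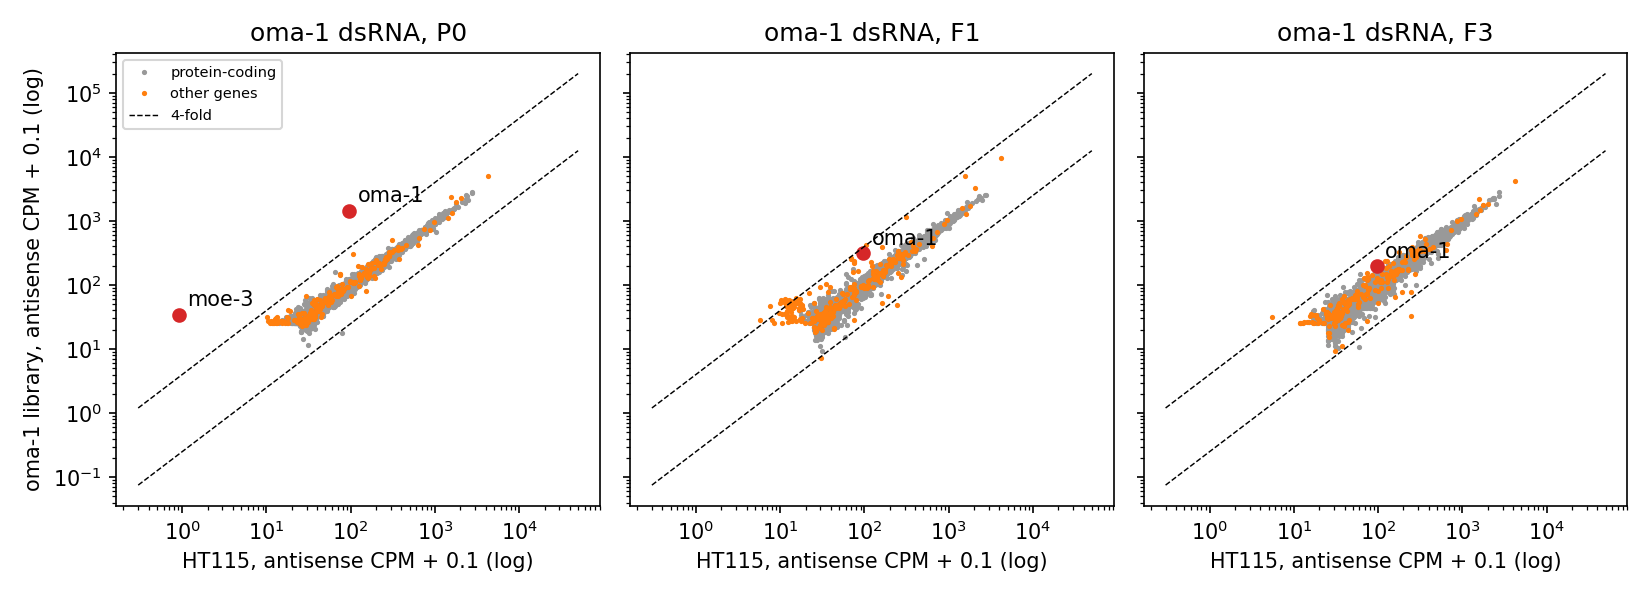
Antisense CPM plus 0.1 of each gene on HT115 (horizontal log axis) and in P0, F1 or F3 (vertical log axis, 1 panel each), protein-coding genes in grey, other genes in orange, with dashed 4-fold lines. In P0, oma-1 and moe-3 lie above the upper line; in F1 the 17 genes above it are all short noncoding RNA genes.

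In F1, small RNAs antisense to short noncoding RNA genes were higher and those against 4 long intergenic noncoding RNAs (lincRNAs) at least 2-fold lower. As a class, the 16 measured lincRNA genes lay within the random range (median log2 -0.04). All 17 genes at least 4-fold higher lay opposite a structural RNA gene, 15 of them opposite a tRNA gene and 2 opposite a small nucleolar or small nuclear RNA gene; they included W04D2.14 (6.26-fold, 4.66 to 8.55), F02D10.11 (5.83), F52E10.10 (5.31), C04C11.8 (5.24), ZK622.6 (5.21), F52E10.7 (5.14), F52E10.9 (5.09), T08B2.14 (5.01), F27D9.9 (4.87) and Y53C10A.16 (4.64). The 2 genes at least 4-fold lower were the lincRNA genes linc-17 (5.07-fold lower, 4.45 to 5.79) and linc-14 (4.25-fold lower, 3.02 to 6.14). They were followed by efl-3, an E2F-like transcription factor gene (3.91-fold lower, 3.08 to 5.01), by the glutamate receptor gene glr-2 at 0.303 times the reference, and by Y53F4B.45 (0.328), linc-24 (0.351), col-60 (0.380), F31E9.11 (0.384), T28D6.4 (0.386) and Y61A9LA.4 (0.450). In F1, oma-1 at 3.28-fold was below that threshold.

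Outside the random range in F1 were 7 lists. ERGO-1 targets were lower (median log2 -0.40, 3 higher and 5 lower), with K02E2.6 at 0.480 (0.448 to 0.514) and C44B11.6 at 0.489 (0.460 to 0.521). All 6 measured cuticle genes were lower (-0.59), among them col-111 at 0.695 and col-38 at 0.621. Kinetochore, centrosome and mitosis genes (-0.11, 13 higher and 49 lower; cyb-1 0.761, kbp-5 0.794, klp-7 0.860) and oocyte and embryo regulators (-0.13, 11 higher and 24 lower; cpg-2 0.728, pos-1 0.730) were lower. X-linked genes were higher (0.27, 97 higher and 46 lower), led by the histone demethylase gene jmjd-3.3 (2.47-fold, 2.22 to 2.75) and F28H6.4 (2.43-fold, 2.17 to 2.74), as were F-box and BATH genes (0.07, 44 higher and 28 lower), although fbxa-139 stood at 0.537 and fbxa-24 at 0.574. The X-linked list was within the random range with no minimum level (percentile 45.5). Ribosomal protein genes were near 0 (0.02, 39 higher and 32 lower), with the abundant rpl-34 and rpl-13A at 1.40 and 1.39. That list was within the random range after thinning (percentile 94.25) and by the mean (85.7), as was the F-box list by the mean (91.0). The germline regulators named in advance stood between 0.854 (mex-5) and 1.01 (ego-1), with wago-4 at 0.940, gld-1 at 1.00, pgl-1 at 0.930, csr-1 at 0.904 and hrde-1 at 0.914, apart from pos-1. Among protein-coding genes alone 0 were at least 4-fold higher and 0 lower, a setting chosen after seeing the data. Against the first untreated library, 380 genes were higher and 239 lower. There the oocyte, cuticle and F-box lists lay on the other side, and the ERGO-1 targets (percentile 28.5) and kinetochore genes (96.5) lay within the random range.

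In F3, the lincRNA gene linc-17 and efl-3 were lower still, and linc-59 was the only gene at least 4-fold higher. Small RNAs against linc-17 were 7.54-fold lower (6.59 to 8.67), those against efl-3 5.59-fold lower (4.37 to 7.21), and those against linc-59 were 5.84-fold higher (4.16 to 8.39). The next lowest were T16A1.9 at 0.298 times the reference, linc-14 (0.301), linc-16 (0.309), the neuropeptide receptor gene npr-11 (0.312), F49B2.3 (0.323), fbxb-37 (0.336), the homeobox gene irx-1 (0.339) and R07H5.9 (0.354). The next highest were Y81B9A.1 (2.89-fold, 2.44 to 3.45), F16F9.4 (2.44), F28H6.4 (2.43), lin-15A (2.35, 1.96 to 2.82), ucr-2.1 (2.32), C38D9.13 (2.29), T04C12.30 (2.23), suca-1 (2.203) and F27D9.9 (2.19). With oma-1 at 2.05-fold, these genes differed from HT115 by more than the target did.

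In F3, 8 lists lay outside the random range. ERGO-1 targets were lower by the widest margin (median log2 -0.93, 1 higher and 7 lower), with C44B11.6 at 0.522 (0.494 to 0.552), K02E2.6 at 0.529 (0.498 to 0.562), fbxb-37 at 0.336 and C40A11.10, annotated as mir-8199, at 0.409. All 6 cuticle genes were again lower (-0.48; col-60 0.510, col-45 0.584), as were neuron genes (-0.38, 3 higher and 6 lower; unc-10 0.457, egl-21 0.654, against nlp-81 at 1.35), kinetochore, centrosome and mitosis genes (-0.14, 11 higher and 51 lower; klp-7 0.739, hcp-3 0.757) and ribosomal protein genes (-0.26, 6 higher and 65 lower; rps-3A 0.629, rpl-22 0.679, against rpl-13A at 1.23). X-linked genes (0.31, 83 higher and 58 lower), F-box and BATH genes (0.15, 49 higher and 25 lower) and histones (0.09, 15 higher and 8 lower; his-55 1.61, his-25 0.662, hil-8 1.08) were higher. The germline regulators named in advance stood at 0.954 (wago-4), 0.901 (pos-1), 0.834 (mex-5), 1.03 (gld-1), 0.956 (pgl-1), 0.840 (csr-1), 0.997 (ego-1) and 0.979 (hrde-1). Weighted trimmed mean (TMM) scaling moved the median of all genes by 0.11 on the log2 scale in F3 and by less in P0 and F1. With no minimum the X-linked list lay on the other side of the random lists (percentile 0), and by the mean the histones (97.45) and neuron genes (2.58) lay within the range. Against the first untreated library, 250 genes were higher and 202 lower. There the cuticle, ribosomal and X-linked lists lay on the other side, and the ERGO-1 (percentile 2.54), kinetochore (82.6) and F-box lists (12.8) lay within the random range.

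**Figure D3:**
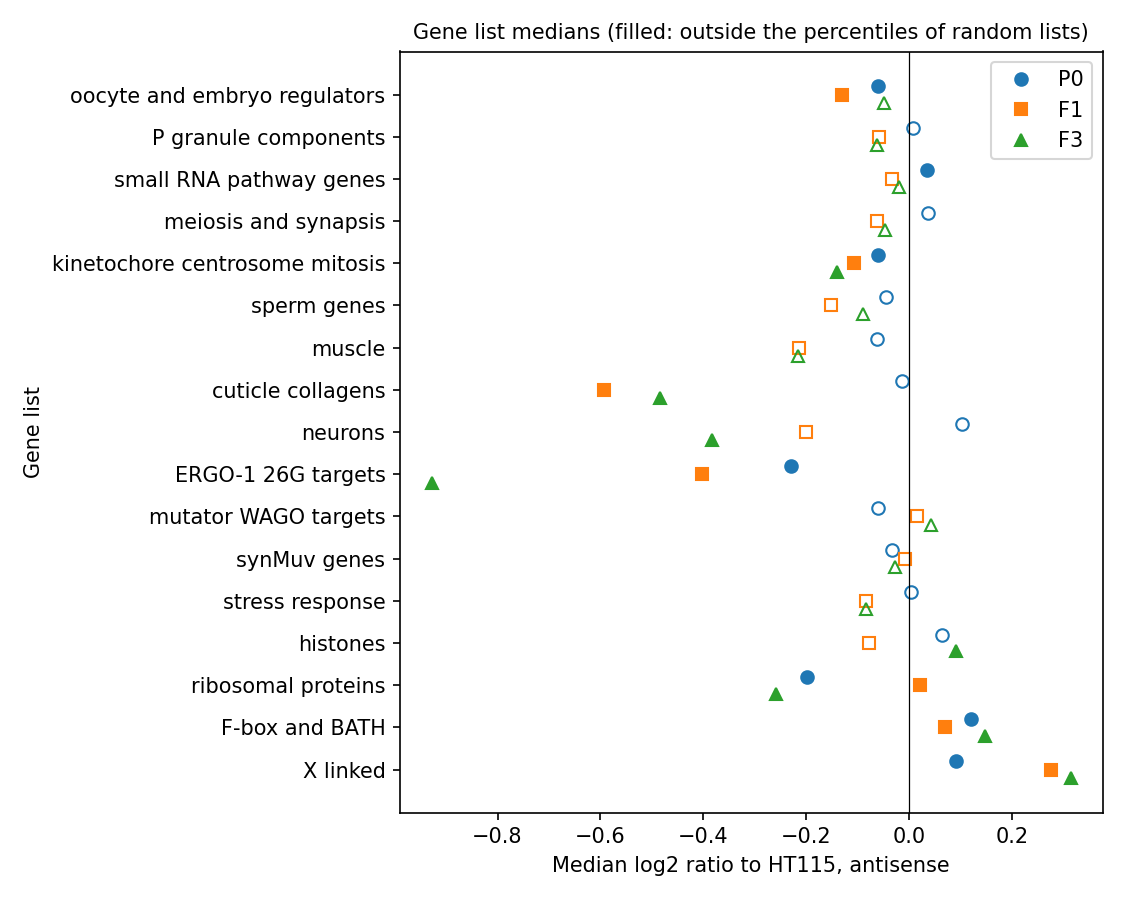
Median log2 ratio to HT115 (horizontal axis) of each gene list with a median in all 3 generations, for P0 (circles), F1 (squares) and F3 (triangles); filled symbols lie outside the percentiles of 10000 random lists. The ERGO-1 targets lie at -0.23, -0.40 and -0.93, and the X-linked genes at 0.09, 0.27 and 0.31. Compared directly, F3 over F1, ERGO-1 targets had a median of -0.03 (4 higher and 4 lower, percentile 18.8). X-linked genes had -0.06 there (53 higher and 86 lower), so a steady change over the generations is not shown.

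The other lists lay within the random range in these generations. Their medians in P0, F1 and F3 were 0.01, -0.06 and -0.06 for P granule components, 0.04, -0.06 and -0.05 for meiosis and synapsis genes, -0.04, -0.15 and -0.09 for sperm genes, -0.06, -0.21 and -0.22 for muscle genes, -0.06, 0.02 and 0.04 for mutator targets, -0.03, -0.01 and -0.03 for synMuv genes and 0.00, -0.08 and -0.08 for stress genes. Further values within the range were 0.10 and -0.20 for neuron genes and 0.06 and -0.08 for histones in P0 and F1, -0.03 and -0.02 for small RNA pathway genes in F1 and F3, -0.05 for oocyte and embryo regulators in F3 and -0.01 for cuticle genes in P0. Some of these lists lay outside the range under other settings. Neuron genes in F1 were below it after thinning (percentile 1.69), by the mean (0.78), with no minimum (0.19), without prefix families (0.86) and against the first untreated library (0.09). With no minimum, muscle genes were below it in P0 (0), F1 (0.02) and F3 (0), and above it against the first untreated library (99.9, 100 and 100). Intestine genes and piRNAs had 0 measured members, and microRNAs and chemoreceptors at most 2.

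Few genes were shared by the 3 generations. Of 5934 genes, 0 were at least 4-fold from HT115 in the same direction in P0, F1 and F3, and 17 were at least 2-fold higher in all 3, oma-1 among them. A gene entered this count at 25 CPM in any of the 4 libraries, so some of the 17 are below the minimum in 1 or more of the comparisons above, where 19 genes were at least 2-fold higher in F3. F02D10.11, F52E10.10, F52E10.7, C04C11.8, F27D9.9 and F59C12.7 of these lie opposite tRNA genes, and T08B2.14 and W04D2.14 opposite small nucleolar RNA genes. Libraries simulated with counting error alone gave 0 such genes. They hold no variation between libraries, and all 3 comparisons share the HT115 library, so no excess was shown. Across 5953 genes the antisense levels on HT115 had Spearman correlations of 0.991 with P0, 0.983 with F1 and 0.981 with F3, and those after lin-15b RNAi correlated at 0.815 to 0.824 with these 4 libraries. Genes are not replicates, and these values only describe the libraries.

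Small RNAs against lin-15B were higher after lin-15b RNAi, as were reads of muscle, intestine, cuticle, ribosomal protein and histone genes with both strands counted, most of them not antisense. The gene lin-15B (WBGene00023497, chromosome X, 15726123 to 15732025, plus strand) encodes a synMuv protein that represses germline genes in somatic cells. It had 11802 reads over both strands after RNAi (1250.3 CPM) against 2122 in the first untreated library (187.6 CPM), a fold of 6.66 (6.36 to 6.98), above 99.8% of genes of similar abundance. After RNAi 96.4% of these reads were antisense (Wilson interval 96.0 to 96.7), at 1722 CPM (1691 to 1754); the antisense level was 75.6 CPM on HT115, 91.4 in P0, 114 in F1 and 112.3 in F3. The neighbouring lin-15A (WBGene00023498, 15731968 to 15735365, plus strand), whose start overlaps the end of lin-15B so that reads there could be counted for either, stood at 1.40-fold (1.20 to 1.65). Relative to HT115, antisense levels in P0, F1 and F3 were 1.21-fold, 1.51-fold and 1.49-fold for lin-15B and 1.93-fold, 1.96-fold and 2.35-fold for lin-15A. Set against HT115, a reference from the other set of libraries, the log2 ratio of lin-15B was 4.05 over both strands and 4.49 for antisense reads, against 2.74 here.

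Of 5818 genes, 47 were at least 4-fold higher and 12 at least 4-fold lower after lin-15b RNAi. The highest were the heat shock genes F44E5.5 (20.5-fold, 15.4 to 27.9), hsp-16.1 (17.6-fold, 12.1 to 26.6), F44E5.4 (13.6-fold, 10.4 to 18.1), hsp-16.49 (12.8) and hsp-16.48 (12.4), which are near-identical pairs and therefore uncertain one by one, then MTCE.20 (9.77), the collagen genes col-81 (9.64, 7.88 to 11.9) and col-129 (7.89), and rpl-38 (7.84) and rpl-39 (7.02). The lowest were B0361.13 (14.2-fold lower, 9.23 to 22.9), Y55D5A.1 (9.58-fold), Y36E3A.2 (7.11-fold), mir-54 (6.86-fold), T05E11.9 (5.97-fold), mir-260 (5.12-fold), Y71F9B.13 (5.02-fold), T28B8.1 (4.78-fold), linc-45 (4.56-fold) and K06B9.6 (4.42-fold). Apart from lin-15B, 42 of the 46 higher genes had under 50% antisense reads, as did 17.7% of all genes measured. Among the 1750 genes with at least 90% antisense reads, a restriction chosen after seeing the data, 5 were higher (lin-15B, rrn-4.2, rrn-4.3, rrn-4.4 and Y39G10AR.26) and 7 were lower, among them T05E11.9, K06B9.6 and ZK1067.3.

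**Figure D4:**
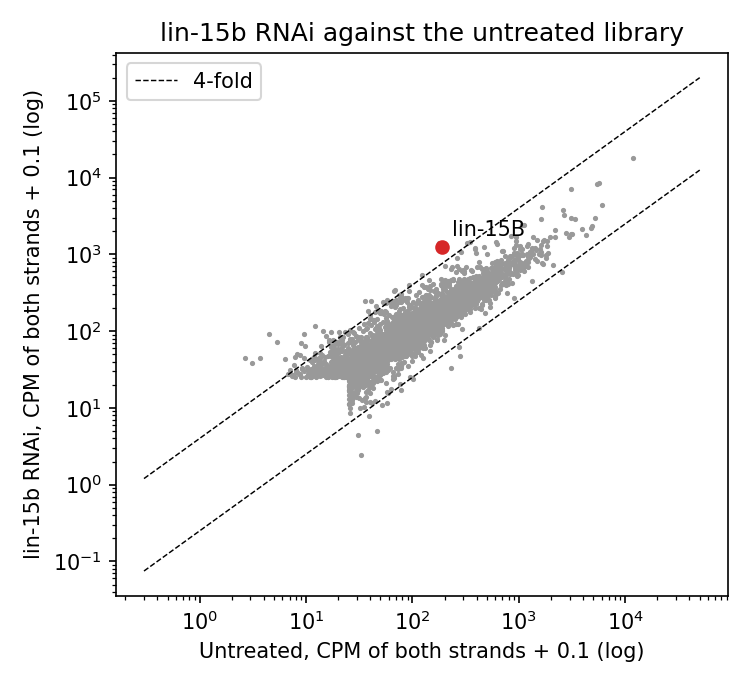
CPM of both strands plus 0.1 of each gene in the first untreated library (horizontal log axis) and after lin-15b RNAi (vertical log axis), with dashed 4-fold lines and lin-15B in red. The target lies above the upper line at 1250.3 against 187.6 CPM, with 46 other genes.

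By list, muscle, intestine and cuticle genes were higher after lin-15b RNAi, while neuron genes were lower (median log2 -0.61, 3 higher and 10 lower; ric-19 3.52-fold and nlp-62 2.38-fold lower). All 17 measured intestine genes were higher (median log2 1.35), among them the yolk genes vit-6 (2.29-fold), vit-2 (2.55) and vit-1 (4.18), whose paralogs share sequence, and cpr-5 (5.59). Muscle genes (1.502, 22 higher and 2 lower) included unc-54 (3.74-fold), unc-15 (4.36), unc-27 (5.60, 4.75 to 6.64) and tnt-2 (2.61), and cuticle genes (1.70, 31 higher and 4 lower) included col-140 (3.48) and col-160 (3.26). Ribosomal protein genes (0.99, 76 higher and 1 lower; rpl-5 2.99), histones (1.10, 56 higher and 6 lower; his-1 4.73, his-63 4.704, his-24 0.704), microRNAs (1.00, 17 higher and 6 lower; mir-82 2.68, mir-235 6.32), stress genes (0.28, 12 higher and 7 lower; hsp-1 1.11, atm-1 0.671) and X-linked genes (0.39, 176 higher and 82 lower; rpl-23A.1 6.90, vit-5 1.77) were higher as well. The median antisense share of the measured members was 0.216% for muscle, 0.00732% for intestine, 0% for cuticle, 21.8% for ribosomal protein and 11.56% for histone genes. Over antisense reads against HT115, from the other set of libraries, ribosomal protein genes were lower (median log2 -1.03, percentile 0, 10 higher and 62 lower), with 0.743% of antisense reads against 1.27%. Histones were higher there as well (0.69, 14 higher and 8 lower). HT115 against the first untreated library has no target, yet muscle (0.84), ribosomal protein (0.81), histone (1.14) and microRNA lists (3.03) were above the random lists. Neuron genes (-0.28) were below them. Intestine (0.56), cuticle (0.46) and stress genes (0.36) lay within them, and X-linked genes (0.04) below. Both comparisons share the first untreated library, so these shifts cannot be credited to lin-15b RNAi alone.

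Of the lists of germline genes and small RNA loci, some were higher and some lower with both strands counted. Oocyte and embryo regulators were higher (0.30, 26 higher and 9 lower; mex-3 2.01, cpg-2 1.87, cbd-1 1.57) and so were mutator targets (0.37, 8 higher and 3 lower; F58H7.5 1.94, F37D6.3 1.08, against F55C9.3 at 0.4996). The median antisense share of the measured oocyte and embryo regulators was 54.5%. Over antisense reads against HT115, from the other set of libraries, their median log2 ratio was -0.35 (9 higher and 26 lower), within the random range (percentile 14.2). Meiosis and synapsis genes were lower (-0.18, 14 higher and 22 lower; cosa-1 0.479, chk-2 0.722, against zim-1 at 1.51), as were all 7 ERGO-1 targets (-1.47; C36A4.11 3.84-fold lower, 3.59 to 4.115, and Y37E11B.2 2.78-fold lower). Within the random range were P granule components (-0.06, 11 higher and 16 lower), small RNA pathway genes (-0.07, 22 and 35), kinetochore, centrosome and mitosis genes (-0.09, 22 and 38), sperm genes (0.07, 5 and 3), synMuv genes (-0.02, 11 and 16), F-box and BATH genes (-0.04, 28 and 38) and piRNAs (0.45, 9 and 2), with 1 chemoreceptor gene measured. Germline regulators named in advance stood at 0.967 (wago-4), 1.43 (pos-1), 1.48 (mex-5), 1.37 (gld-1), 0.886 (pgl-1), 0.935 (csr-1), 1.00 (ego-1), 1.11 (hrde-1), 1.25 (oma-1) and 1.31 (oma-2). Against HT115 over both strands, 157 genes were higher and 133 lower. There the mutator targets and microRNAs lay on the other side of the random lists, and the oocyte (percentile 51.9), meiosis (17.7), neuron (53.5) and stress lists (37.1) lay within them. The mutator targets were also within the range by their mean (76.3), and the meiosis genes among mostly antisense genes (20.8). With no minimum level the neuron genes (93.4) and mutator targets (95.3) lay within it. The X-linked genes (49.995) and microRNAs (50) were then not placed, because tied medians give such percentiles.

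The 2 libraries without RNAi differed more from each other than any treated library did from its own reference, in a comparison with no target. Of 6170 genes 158 were at least 4-fold higher on HT115 and 177 at least 4-fold lower. Over both strands the log2 ratios had a standard deviation across genes of 1.09, against 0.57 for lin-15b RNAi. For P0, F1 and F3 it was 0.22, 0.31 and 0.29, over antisense reads alone. With both strands counted throughout, the Spearman correlation was 0.820 between these 2 libraries and 0.945 between lin-15b RNAi and the first untreated library. For HT115 with P0, F1 and F3 it was then 0.987, 0.946 and 0.975. The highest were the microRNA gene mir-1 (at least 445-fold) and T09B4.14 opposite it (at least 379.9-fold), each with 0 reads in the first untreated library, F16A11.6, which overlaps mir-71 and had 2 reads there (1666-fold, 461 to 13766), mir-71 (630.1-fold, 319 to 1460.5) and mir-78 (295-fold, 101 to 1435). The lowest were F28D9.5 (at least 209-fold lower) and the piRNA gene 21ur-1684 (at least 100.4-fold lower), both with 0 reads on HT115, Y65B4BM.2 with 3 reads (137-fold lower, 46.5 to 665) and linc-76, at 12.8 against 1165 CPM (91.2-fold lower, 76.2 to 110). Among the targets, lin-15B stood at 0.403 times the first untreated library (0.369 to 0.439) and oma-1 at 1.07 (0.982 to 1.16). These libraries also belong to sets counted on different gene annotations, so the bacteria and the set cannot be told apart. Of the genes at least 4-fold apart 47.2% were higher, against 29.7% under median-of-ratios scaling and 17.5% under TMM scaling (77 higher and 363 lower), and they moved the median of all genes by -0.27 and -0.59.

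Between these libraries 11 lists lay outside the random range. MicroRNAs were higher on HT115 (median log2 3.03, 29 higher and 9 lower) and all 5 measured piRNAs lower (-5.80); both medians were the same with the member at 0 reads set at its bound. Histones (1.14, 55 higher and 13 lower; his-4 6.46-fold, his-74 5.53), ribosomal protein genes (0.81, 66 and 12; rpl-34 9.96), mutator targets (1.06, 8 and 3; K02E2.6 7.66, F58H7.5 4.57) and muscle genes (0.84, 18 and 3; act-4 3.33, against tnt-2 4.04-fold lower) were higher under each scaling. Muscle genes were within the random range by the list mean (percentile 90.7) and with no minimum (93.2). Neuron genes were lower (-0.28, 6 and 8; nlp-62 5.04-fold and ric-19 4.74-fold lower). Small RNA pathway genes (0.36, 43 and 14; smut-1 3.40) and kinetochore, centrosome and mitosis genes (0.29, 46 and 16; icp-1 3.09, cdk-1 4.53-fold lower) had medians that turn negative once TMM shifts all ratios, and F-box and BATH genes (0.12, 43 and 33; bath-24 24.2-fold lower) and X-linked genes (0.04, 128 and 116; Y7A5A.10 18.5-fold lower) had medians below the random lists; the F-box list was within them under TMM scaling (percentile 2.99), without the most abundant genes (2.96) and after thinning (3.35). Within the range were oocyte and embryo regulators (0.27), P granule components (0.27), meiosis and synapsis genes (0.29), sperm genes (-0.20), intestine genes (0.56), cuticle genes (0.46), ERGO-1 targets (0.55), synMuv genes (-0.04) and stress genes (0.36), with 2 chemoreceptor genes measured. Germline regulators named in advance stood at 1.19 (wago-4), 1.43 (pos-1), 1.21 (mex-5), 1.90 (gld-1), 0.749 (pgl-1), 1.96 (csr-1), 1.23 (ego-1), 1.03 (hrde-1) and 0.544 (oma-2), and lin-15A at 0.840.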

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

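The differences in this part were not tested, because each group has 1 library. F32A11.1 was picked because it overlaps moe-3, after the moe-3 levels were seen; the bounds of the overlap test were written before its sense reads were compared. The tests of sharing with oma-1 in a fixed proportion and of F32A11.1 as the whole source were chosen after the result was seen.

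Sense reads of oma-1 were 1.57 times the HT115 level in P0 (1.38 to 1.78), above 98.8% of genes of similar abundance, and 1.00 and 0.992 times in F1 and F3. The feeding dsRNA holds both strands, so antisense reads do not exclude fragments of it. Sense reads of the paralog oma-2 were also higher, at 1.33-fold in P0 (1.17 to 1.52) and 1.30-fold in F1 (1.15 to 1.48), within the upper part of genes of similar abundance (percentiles 91.8 and 89.4). In F3 they stood at 1.14-fold.

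Reads antisense to moe-3 were higher in P0 alone: its log2 ratio to HT115 was 5.28 in P0, -0.9996 in F1 and -0.23 in F3, where oma-1 stayed above the reference. If the moe-3 reads were shared with oma-1 in a fixed proportion through similar sequence, F1 and F3 together should hold 58.7 of them; they held 7, with an upper bound of 14.4, which argues against it. F32A11.1 overlaps the end of moe-3 on the other strand, and its sense reads numbered 219 in P0 where 186 were expected at HT115 levels. The upper bound of that rise, 92.4 reads, met neither of the bounds set in advance, so a part from this gene stays open. As the whole source it is argued against, because the moe-3 gain of 202 reads has a lower bound of 169. This holds only if reads in the overlap were counted for both genes or divided evenly between them, which was not checked.

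Sharing that differs between generations, and dsRNA acting on moe-3 in the treated generation, were not tested. Where along moe-3 the reads lie would separate these, and read positions were not analysed here.

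Other genes were lower than the reference in some of the 3 generations and near it in others. The log2 ratios of efl-3 were 0.0085, -1.96 and -2.47 in P0, F1 and F3, and those of linc-14 were 0.019, -2.08 and -1.72, so that both were near the reference in P0 and lower in both later generations. Those of vang-1 were -2.15, 0.034 and -1.27, lower in P0 and F3 and near the reference between them. The growth notes in the labels also differ between these libraries, and the generation and the growth conditions were not separated.

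List medians with different places were those of histones (0.064, -0.078 and 0.091 in P0, F1 and F3), neuron genes (0.10, -0.20 and -0.38), ribosomal protein genes (-0.20, 0.021 and -0.26) and small RNA pathway genes (0.036, -0.034 and -0.020). The histone and small RNA pathway medians are smaller than the 0.11 by which TMM scaling moved all genes in F3.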

How the results depend on the processing

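No paired analysis was possible because each group has 1 library, and the result comes from no test. Among the main values, 178 stayed the same under the alternatives, 82 moved and 2 reversed. Among the others 732 stayed the same, 39 were weaker, 35 stronger, 15 reversed and 1 moved. A gene ratio was the same inside its main interval, a count when near its main number, and a list when still outside on its side or still within. A gene ratio could reverse only where its main interval lay to one side of no difference. These totals are therefore not a rate of robustness.

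Values below that use the first untreated library as reference count both strands, and cross from one set of libraries to the other. There oma-1 had log2 ratios of 3.35 in P0, 1.25 in F1 and 0.84 in F3, and oma-2 had -0.62, -0.39 and -0.67. The neighbour spr-2 stood at 1.18, 1.47 and 1.55, and rad-54.L2 at -0.34, -0.54 and -0.25; the P0 value of spr-2 and the F3 value of rad-54.L2, whose main intervals lie to one side of no difference, reversed. The cause was not tested. With HT115 as the reference lin-15B reached 4.05 over both strands and, for antisense reads in a setting chosen after seeing the data, 4.49.

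Counting both strands against HT115 gave oma-1 3.26 in P0, 1.16 in F1 and 0.75 in F3. Antisense counts over the total of both strands, chosen after seeing the data, gave oma-1 3.74 in P0 and 1.23 in F1, and oma-2 -0.46 in F1. TMM scaling gave rad-54.L2 0.24 in F3 and lin-15B 2.66. Over all alternatives oma-1 stayed higher, from 3.26 to 3.90 in P0, 1.16 to 1.77 in F1 and 0.75 to 1.14 in F3, and lin-15B from 2.66 to 4.49. C27B7.2 kept its label under every alternative.

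The number of genes at least 4-fold apart depended on the minimum level, the reference and the fold. With the other library without RNAi as reference, 157 genes were higher and 133 lower for lin-15b RNAi, 216 and 183 for P0, 380 and 239 for F1, and 250 and 202 for F3. With no minimum the counts were 1639 and 1361 for lin-15b RNAi, 396 and 2477 for P0, 411 and 2655 for F1, 610 and 2024 for F3, and 6751 and 950 for HT115 against the first untreated library, as genes with few reads then enter. With the higher minimum they were 20 and 5 for lin-15b RNAi, 1 and 0 for P0, 0 and 1 for F1, and 0 and 1 for F3, and 58 genes were higher on HT115 than in the first untreated library. At 2-fold they were 367 and 105 for lin-15b RNAi, 31 and 2 for P0, 87 and 25 for F1, 19 and 34 for F3, and 1142 and 603 for HT115 against the first untreated library.

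Other settings moved fewer counts. Totals without the most abundant genes and the target gave 2 lower genes in P0, and the larger pseudocount gave 1 lower gene in F1. With protein-coding genes only, chosen after seeing the data, 2 genes were lower in P0, 0 were higher and 0 lower in F1, 0 were higher and 1 lower in F3, and 105 were higher on HT115 than in the first untreated library. Genes with at least 90% antisense reads, also chosen after seeing the data, gave 5 higher and 7 lower for lin-15b RNAi and 5 lists outside the random range. For HT115 against the first untreated library TMM scaling gave 77 higher and 363 lower genes, and median-of-ratios scaling gave about 1.0e2 higher.

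Lists outside the random range numbered 14 in P0 and 13 in F1 with the first untreated library as reference, 4 in F3 and 6 for HT115 against the first untreated library without prefix families, and 7 in that comparison with no minimum. Several lists lay on the other side of the random lists against the other reference. Their percentiles were 0.15 for mutator targets and 0 for microRNAs after lin-15b RNAi. In P0 they were 98.5 for oocyte and embryo regulators, 98.7 for kinetochore, centrosome and mitosis genes, 100 for ribosomal protein genes, 2.23 for F-box and BATH genes and 0.07 for X-linked genes. In F1 they were 99.7 for oocyte and embryo regulators, 100 for cuticle genes and 0.03 for F-box and BATH genes, and in F3 100 for cuticle genes, 100 for ribosomal protein genes and 0.55 for X-linked genes. Other lists came to lie within the random range against that reference. After lin-15b RNAi these were oocyte and embryo regulators (51.9), meiosis and synapsis genes (17.7), neuron genes (53.5) and stress genes (37.1). They were ERGO-1 targets in P0 (38.3), F1 (28.5) and F3 (2.54), kinetochore, centrosome and mitosis genes in F1 (96.5) and F3 (82.6), and F-box and BATH genes in F3 (12.8).

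Further lists were lost under other settings. The X-linked list in P0 was within the range with totals without the most abundant genes (87.1), after thinning (93.1) and with protein-coding genes only (92.5). By the list mean the same held for mutator targets after lin-15b RNAi (76.3), small RNA pathway genes in P0 (95.2), ribosomal protein genes (85.7) and F-box and BATH genes (91.0) in F1, neuron genes (2.58) and histones (97.45) in F3, and muscle genes on HT115 against the first untreated library (90.7). In that comparison the F-box list was within the range under TMM scaling (2.99), with totals without the most abundant genes (2.96), after thinning (3.35), with protein-coding genes only (5.52) and with no minimum (74.9). Ribosomal protein genes in F1 were within it after thinning (94.2), small RNA pathway genes in P0 with no minimum (87.7), and meiosis genes among mostly antisense genes after lin-15b RNAi (20.8). The cause was not tested.

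With no minimum the X-linked genes were at percentile 0 in P0 and in F3, the reverse of the main result, and within the range in F1 (45.5). After lin-15b RNAi the neuron genes (93.4) and mutator targets (95.3) were then within it, and X-linked genes and microRNAs stood at 49.995 and 50. On HT115 against the first untreated library, small RNA pathway genes (91.2), kinetochore genes (89.7), muscle genes (93.2), neuron genes (97.13) and X-linked genes (15.2) were within it, and piRNAs stood at 50. A gene with 0 reads in both libraries has a log2 ratio of 0 in this setting, and tied medians are split evenly. Percentiles at or next to 50 are what tied medians give, so this setting does not place those lists. The cause of the other changes was not tested.

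Lists within the range in the main comparison came to lie outside it under some settings. Against the other reference these were small RNA pathway genes (0.09), kinetochore genes (0.26) and piRNAs (100) after lin-15b RNAi, sperm genes in P0 (2.29) and F1 (1.79), neuron genes in P0 (0.745) and F1 (0.09) and histones in P0 and F1 (100). So were mutator targets (99.8, 99.64 and 99.94) and muscle genes (99.9, 100 and 100) in P0, F1 and F3. With no minimum they were sperm genes after lin-15b RNAi (99.83), in F3 (99.96) and on HT115 (0), muscle genes in P0 (0), F1 (0.02) and F3 (0), stress genes in P0 (97.95), neuron genes (0.19) and histones (99.67) in F1 and ERGO-1 targets on HT115 (98.77). By the mean they were muscle genes in P0 (0.58), neuron genes in F1 (0.78), oocyte and embryo regulators in F3 (1.82) and F-box and BATH genes after lin-15b RNAi (0.51). Neuron genes in F1 were also outside after thinning (1.69) and without prefix families (0.86). So were ERGO-1 targets on HT115 without the most abundant genes (99.51), after thinning (99.6) and with protein-coding genes only (99.63), and kinetochore genes among mostly antisense genes after lin-15b RNAi (1.69). The cause was not tested.

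Without the most abundant genes, protein-coding genes held 97.2% of the reads of the first untreated library and 94.9% on HT115, microRNA genes 0.305% and 0.572%, and ribosomal RNA genes 0.345% and 0.332%. Both strands were already counted in the main comparison for lin-15B, so that alternative was not run for it. HT115 against the first untreated library has no further reference, and lists made only of prefix families have no value without them.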

Other observations

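Beyond the listed genes, reads antisense to the class of short noncoding RNA genes were higher in all 3 generations, with median log2 ratios of 0.63 in P0 (82 genes), 1.33 in F1 (107) and 0.46 in F3 (60), where 26, 70 and 6 were at least 2-fold higher. A gene enters when the higher of the 2 libraries reaches 25 CPM, so the sets differ and genes that are higher in a library enter more easily. Transposons lay near the reference in F3 at 0.09 over 114 genes, above the random lists. After lin-15b RNAi the 18 measured lincRNA genes were lower, with a median of -0.41, and 4 of them were at least 2-fold lower; over antisense reads against HT115 the class median was -0.26, within the random range (percentile 63.8).

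LincRNA genes differed from one another over the generations. Antisense levels of linc-17 were 246, 212, 48.4 and 32.6 CPM on HT115 and in P0, F1 and F3, and those of linc-16 were 247, 226, 153 and 76.4. Those of linc-14 were 30.4, 30.8, 7.16 and 9.17 CPM and those of linc-24 190, 187, 66.6 and 76.4. The levels of linc-59 went the other way, at 5.41, 6.63, 15.4 and 31.6 CPM. As a class the lincRNA genes lay within the random range in P0, F1 and F3, with a median of -0.12 in F3. Some of these levels lie outside the naming rule and were chosen after their values were seen.

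Of the tests below, that of a single scaling factor was written before its result was seen, and those of sense fragments and of opposite structural RNA genes were chosen after the result was seen. Among the genes at least 4-fold higher after lin-15b RNAi, without lin-15B, 91.3% had under 50% antisense reads, with a median antisense share of 0.262%. Fragments of messenger and structural RNA in the sense direction are therefore a possible explanation for most of them, in place of secondary small RNAs. A single wrong scaling factor is argued against, because 39 genes stayed at least 4-fold higher after TMM scaling.

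Of the genes at least 4-fold higher in F1, 100% lie opposite a structural RNA gene, against 2.201% of all measured genes and 67.3% of measured noncoding RNA genes. Those opposite a structural RNA gene had a median log2 ratio of 1.61 and other noncoding RNA genes 0.02. This leaves reads of a structural RNA annotated on the opposite strand as a possible explanation, and sense tRNA reads per 1000000 antisense reads were 907 on HT115, 1323 in P0, 2271 in F1 and 1347 in F3. A tRNA read is sense to its own gene and antisense to the gene opposite, so these counts may not be secondary small RNAs.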
